A study of Arabidopsis thaliana with 6 samples.

How the data were processed

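AGO4 ChIP and input DNA were sequenced from 2 to 3 week old seedlings of Col-0, ago4 and nrpe1, 1 library each. Per the labels' protocols, tissue was fixed with 0.5% formaldehyde, DNA was sheared to a mean of 250 bp, and the antibody was raised against amino acids 573 to 924 of AGO4. The ago4 line carries ago4-1, which per the labels was brought into Col-0 from another background. Per the submitters' processing notes, reads were aligned to TAIR9 with Bowtie; the version and settings are not given in the sources used here. The deposited files hold 1 row per alignment, with chromosome, strand, start position, aligned length and a number from 1 to 10, and no normalization. Runs of rows with the number 2 had even lengths in 100% of cases, so the number was taken as the number of places at which a read aligned. It is headed clone, and even runs would also arise from copies of a read, so this reading is an assumption. Against copies, 13511857 nuclear rows of the Col-0 ChIP with the number 1 lay on only 5188892 distinct starts. Aligned lengths were 15 to 80 bases.

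Reads were moved 125 bp in the 3' direction, which is 50% of the mean fragment length, and counted in 200-bp bins on the 5 nuclear chromosomes. Of 595734 bins, 552454 were tested, those in which each input had at least 25% of its own median. Libraries were scaled by their totals over the tested bins. Each bin was tested with a one-sided exact binomial test and Benjamini-Hochberg adjustment, with 1 start added to each scaled count for the fold threshold, and called bins up to 1 bin apart were merged. The folds printed for regions and genes carry no added start. Regions were compared between nrpe1 and Col-0 with a two-sided exact binomial test. Ratios have exact (Clopper-Pearson) 95% intervals, and retained shares have bootstrap intervals over regions (2000 draws). A read that aligned at several places was counted in full at each of them, so regions can share reads. Such reads gave most Col-0 starts in 329 of the 761 regions reported below. The tests and intervals treat bins and regions as independent and do not allow for this. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

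The reported values depart from the plan in 2 choices, the counting of rows and the promoter, described with the gene table. The plan counted the rows as deposited and held 1 row per chromosome, strand and 5' position as the alternative. Because there were up to 3.99 rows per distinct start on average, they are not independent reads and the binomial test on them is not valid. Distinct starts were therefore used for the reported values. Repeats were seen first, but the calls under both settings had been seen before the choice was settled, and both are printed. Also added after the data were seen were the 3 blocks with few ago4 reads, the naming rule repeated outside them, the Col-0 against nrpe1 call and the 20-base setting of the genotype check. Blocks are runs of 500-kb windows in which over 1% of usable 1-kb bins, those with at least 20 distinct starts of 1-hit reads in the Col-0 ChIP, nrpe1 ChIP and Col-0 input, lie under 0.2 of the Col-0 input level in the ago4 ChIP or input, joined over 1 window and extended by 1 window on each side. The requirement on Col-0 and nrpe1 reads makes low bins in those 3 libraries unlikely by construction.

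Gene names and positions came from a gene table of assembly TAIR10.1 with 37899 genes on these chromosomes, 27444 of them protein-coding. The assembly differs in name from TAIR9, so none of its coordinates is printed. Its register was checked against 1-hit Col-0 input coverage: in 116 of 116 blocks of 1 Mb the best offset within 5 kb was at most 200 bp. The same check on ChIP over input put 60 of 116 blocks within 200 bp. The table has no strand and no separate class for transposon genes, so the planned upstream promoter became the 1 kb on either side of a gene, and gene ends were pooled in the profile. The named regions were the 12 in flanks and the 6 beyond them with the highest lower bound of Col-0 over ago4, the 6 with the highest lower bound of nrpe1 over Col-0, the 4 of the reverse call with the highest lower bound, and members of the listed loci with a region or the highest ratio of their list.

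The calling step was tested on simulated counts for the Col-0 against ago4 comparison over 552454 bins, with 50 bins changed at each fold. It recovered 0% at 2-fold, 20% at 3-fold, 62% at 5-fold and 100% at 10-fold, with 0 false and 0 reverse calls. The simulation holds counting error only, not differences between libraries. Retained shares of 0, 50 and 100% were estimated as -0.319, 48.5 and 98.5%. Alternatives covered scaling, bin size, thresholds, the shift, repeats, input rules, depth and multiple hits. Settings that need sequence, on GC content, were not run because no genome was used here.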

Results

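Chromatin immunoprecipitation with an antibody against AGO4, the Argonaute protein that carries small RNAs in RNA-directed DNA methylation, was sequenced from seedlings of wild-type Col-0 *Arabidopsis thaliana*, the ago4 mutant and the nrpe1 mutant. NRPE1 is the largest subunit of RNA polymerase V (Pol V), whose transcripts are thought to recruit AGO4 to chromatin. Each genotype gave 1 ChIP library and 1 input library, 6 libraries in all, so no difference below has a replicate check. The deposited alignments held 28488174 rows for the Col-0 ChIP, 29354601 for the ago4 ChIP and 29548916 for the nrpe1 ChIP. The inputs held 52988367 rows in Col-0, 30726501 in ago4 and 32109546 in nrpe1. On the 5 nuclear chromosomes the ChIP rows fell on 8003870 distinct starts in Col-0, 7093638 in ago4 and 13885158 in nrpe1, where a start is a chromosome, strand and 5' position. Rows per distinct start came to 3.44, 3.99 and 2.04 in these ChIP libraries, against 1.43, 1.48 and 1.32 in the Col-0, ago4 and nrpe1 inputs. Counts below are distinct starts, scaled to the Col-0 ChIP total over the tested bins. Intervals and tests cover counting error only and compare libraries, not genotypes. They do not allow for reads with several hits, which were counted at each place.

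The targeted genes were examined first. AGO4, on chromosome 2, had 502 distinct starts of 1-hit reads in the ago4 ChIP and 875 in the ago4 input, at 2.21 and 1.29 times the density of the 1 Mb on either side. The Col-0 libraries had 2.05 and 1.25 times, so the gene was present in all genotypes. Reads covering a position of AGO4 with at least 20 bases on either side were missing at 650 positions in ago4, against 0 in Col-0 and 2 in nrpe1. The longest such run in ago4 was 97 bp (TAIR9 chromosome 2, 11541523 to 11541619). The median number of such reads was 7 in ago4, 14 in Col-0 and 12 in nrpe1, so depth adds to the ago4 count, and the gene lies in a stretch with few ago4 reads. With 10 bases on either side, the setting tried first, 256 positions of AGO4 lacked a covering read in ago4 and 0 in Col-0. At NRPE1 the check gave no clear break in nrpe1: with 10 bases on either side the lowest count was 2 reads and 0 positions were uncovered. With 20 bases, chosen after that result, 16 positions were uncovered in nrpe1, with a longest run of 5 bp (chromosome 2, 16720512 to 16720516), but 14 were uncovered in Col-0 and 51 in ago4. The nrpe1 label therefore rests on the submitters' description.

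Stretches of chromosomes 1, 2 and 3 held bins with few reads in the ago4 ChIP, and those of chromosomes 1 and 2 also in the ago4 input. In 1-kb bins with enough Col-0 and nrpe1 reads, 649 of 8440 bins on chromosome 2 between 2 and 12 Mb, the stretch that holds AGO4, lay under 0.2 of the Col-0 input level in the ago4 ChIP and 774 did so in the ago4 input. On chromosome 1 between 7.5 and 10.5 Mb the counts were 47 and 46 of 2721 bins. On chromosome 3 between 10 and 16.5 Mb, 315 of 5110 bins were low in the ago4 ChIP and 1 in the ago4 input. Outside these 3 blocks, 3 of 89278 bins were low in the ago4 ChIP. The nrpe1 ChIP had 0 low bins in the blocks and 0 outside. The block rule was set after the data were seen and uses the ago4 ChIP itself. The blocks hold 15.6% of the tested bins, and most values are given below both for all bins and outside the blocks.

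**Figure D1:**
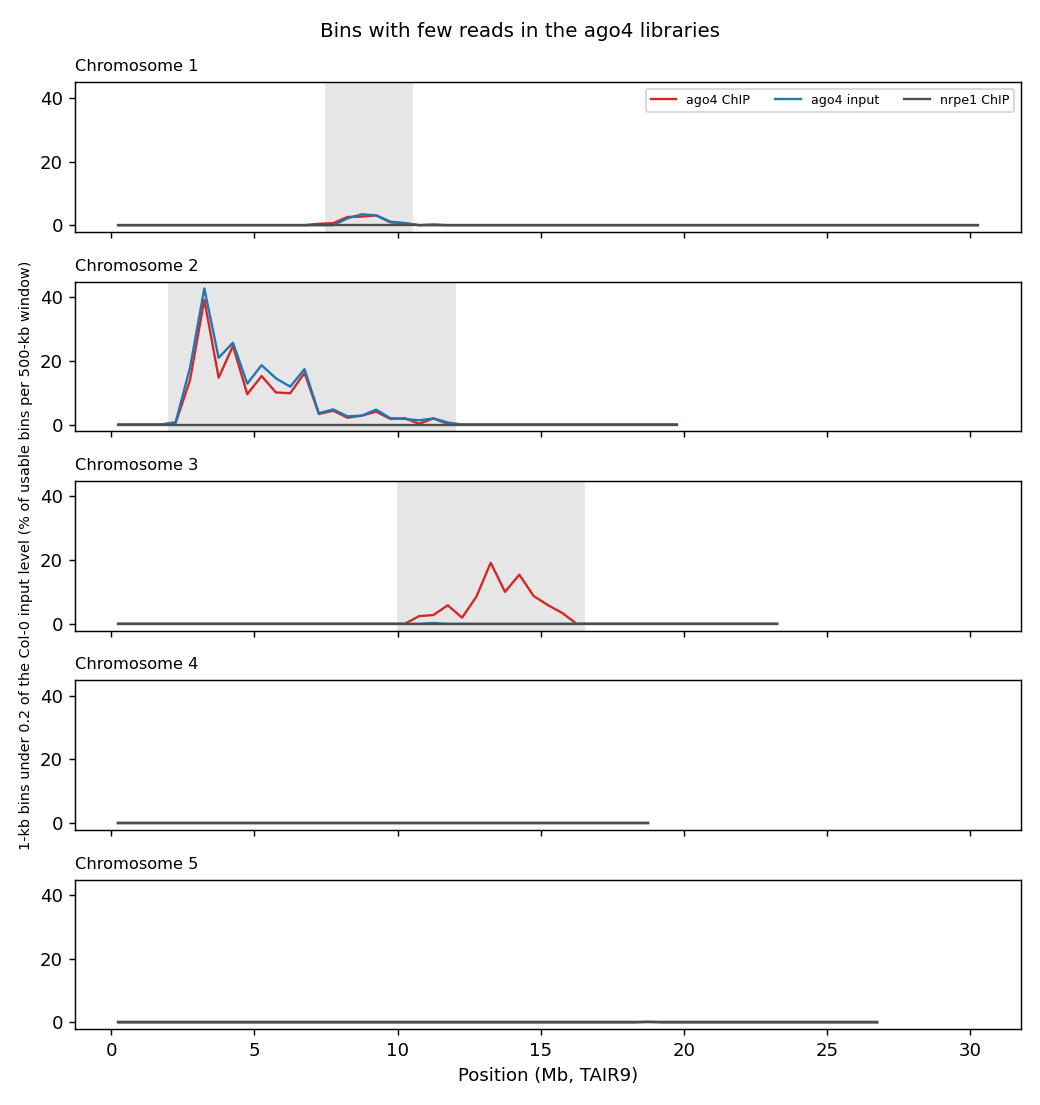
Percentage of usable 1-kb bins per 500-kb window (vertical axis) that lay under 0.2 of the Col-0 input level, along each chromosome in Mb (TAIR9), for the ago4 ChIP, ago4 input and nrpe1 ChIP libraries. Grey areas are the 3 blocks; on chromosome 3 the ago4 ChIP line rises while the ago4 input line stays near 0.

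The first comparison asked where AGO4 ChIP signal in Col-0 exceeded that in ago4, the mutant that lacks normal AGO4 and serves as the antibody control. Outside the blocks, 166 regions passed. A region overlapping RIE1, a RING-type protein gene, and one near MGD1, a galactolipid synthase gene, had the highest lower bounds of the fold among those in flanks. One near ASN1, an asparagine synthetase gene, had a Col-0 over ago4 fold of 6.02 (3.90 to 9.67), close to the median of these regions. Over all 552454 tested bins, 1999 bins in 761 regions had more Col-0 than ago4 ChIP starts, and 595 of the 761 regions lay in the 3 blocks. The reverse rule, ago4 above Col-0, gave 79 bins in 67 regions, of which 51 lay outside the blocks. The median Col-0 over ago4 fold was 5.92 outside the blocks (quartiles 4.10 and 8.67) and the median Col-0 ChIP over input was 3.30. The test was a one-sided exact binomial test per 200-bp bin with Benjamini-Hochberg adjustment, at q under 0.01 and a fold of at least 2 before and after division by the input fold. With the rows as deposited, the setting planned first, 22948 regions passed and 18103 passed in reverse, or 18645 and 16146 outside the blocks. Input alone, without division, gave 980 regions with Col-0 above ago4 and 2162 with ago4 above Col-0, or 380 and 1849 outside the blocks, more than the 166 of the ChIP. The inputs were deeper, with means of 59.7 (Col-0) and 33.5 (ago4) starts per tested bin against 14.1 and 12.6 in the ChIPs. Input and ChIP counts are therefore not on an equal footing.

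By the naming rule fixed before the data were examined, the regions in flanks with the highest lower bounds over all bins included one near BBX15, a B-box protein gene, with 47 Col-0 starts against 0 in ago4 and 11 in nrpe1, and one near AT2G13895 with 111 against 6 and 172. The ago4 input was low there too: the BBX15 region had 57 Col-0 and 13 ago4 input starts and the AT2G13895 region 349 and 51, before scaling. Both regions lay in blocks, and so did 8 of the 12 regions named by this part of the rule in all. All 6 named regions beyond the flanks lay in the chromosome 2 block. The one nearest to AT2G07981 (chromosome 2, 3613601 to 3613800) had 95 Col-0 starts, 1 ago4 start and 122 nrpe1 starts, with 0% of its Col-0 starts from 1-hit reads. Its inputs had 240 starts in Col-0 and 8 in ago4 before scaling, so the low ago4 ChIP count there is not specific to AGO4.

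The rule was repeated outside the blocks, a choice made after the data were seen. The RIE1 region (TAIR9 chromosome 2, 324201 to 324400) had 44 Col-0, 1 ago4 and 8 nrpe1 ChIP starts, a Col-0 over ago4 fold of 39.5 (95% exact interval 6.72 to 1594). The MGD1 region (chromosome 4, 15373401 to 15373600) had 42, 2 and 12 starts and a fold of 18.8 (4.90 to 161). At SAG24, a senescence-associated gene, the region (chromosome 1, 24838601 to 24839200) overlapped the gene and had 141, 16 and 39 starts. The ASN1 region (chromosome 3, 17437201 to 17437800) had 161, 24 and 58 starts. Further flank regions lay near AT1G58602, AT1G51805, AT1G36623, AT5G58510, AT1G67580, RLP46, a receptor-like protein gene, and RBL3, a rhomboid-like protease gene. At CRY3, a cryptochrome gene, 17 Col-0 starts stood against 0 in ago4, at least 5.08-fold higher on a floor of 3 counts over the library, with an exact lower bound of 3.70, and 7 in nrpe1. Beyond the flanks, the region over AT5G52070 and the microRNA gene MIR4245 (chromosome 5, 21161201 to 21162000) had 229, 24 and 31 starts, a fold of 8.56 (5.61 to 13.6). A region within LHCB2.1, a light-harvesting protein gene (chromosome 2, 1823001 to 1823200), had 31, 1 and 7 starts. The region nearest to AT2G03667 (chromosome 2, 1111601 to 1111800) had 24 Col-0 starts, 0 in ago4 and 1 in nrpe1. The others of this kind lay nearest to AT3G26539, AT1G58602 and EXGT-A3.

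In the reverse call the highest lower bounds belonged to a pair of regions at AT1G27555 (chromosome 1, from 9570201 and from 9571001) inside a block, with 157 and 127 ago4 starts against 12 and 12 in Col-0. Regions nearest to AT2G09388, with 56 against 6, and to AT1G40087, with 31 against 2, completed the 4. Outside the blocks the repeat added regions nearest to AT1G39060, AT1G40086 and AT1G66130, the last with 23 ago4, 22 nrpe1 and 2 Col-0 starts.

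The second comparison, the question in the title of the series, asked whether AGO4 ChIP signal at these regions was lower without Pol V. Outside the blocks the nrpe1 ChIP fell to a median of 0.241 of Col-0 (quartiles 0.166 and 0.370), where the ago4 ChIP stood at 0.169. The MIR4245 region was at 0.0774 of Col-0 in nrpe1 (0.0514 to 0.113), RIE1 at 0.104 (0.0423 to 0.223) and MGD1 at 0.163 (0.0783 to 0.316). In 138 of the 166 regions nrpe1 was lower by the two-sided exact binomial test at q under 0.01 and a fold of at least 2, 83.1% (exact interval 76.6 to 88.5), and in 0 it was higher. The share of the Col-0 minus ago4 difference retained in nrpe1 was 8.71% (bootstrap over regions 5.36 to 11.9). Over all 761 regions, 190 were lower in nrpe1 and the retained share was 79.0% (75.2 to 82.5). Inside the blocks, 52 of 595 regions were lower, the median nrpe1 over Col-0 ratio was 0.850 and the retained share was 84.7% (81.1 to 88.5). On reads not used for calling, 24 regions outside the blocks retained -6.05% (-15.6 to 3.17) and 182 inside retained 78.7% (75.6 to 82.7). The counts of regions lower in nrpe1 use the Col-0 starts that chose the regions and were not repeated on starts held out. With the rows as deposited, the share was 44.4% outside the blocks and 64.7% over all.

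**Figure D2:**
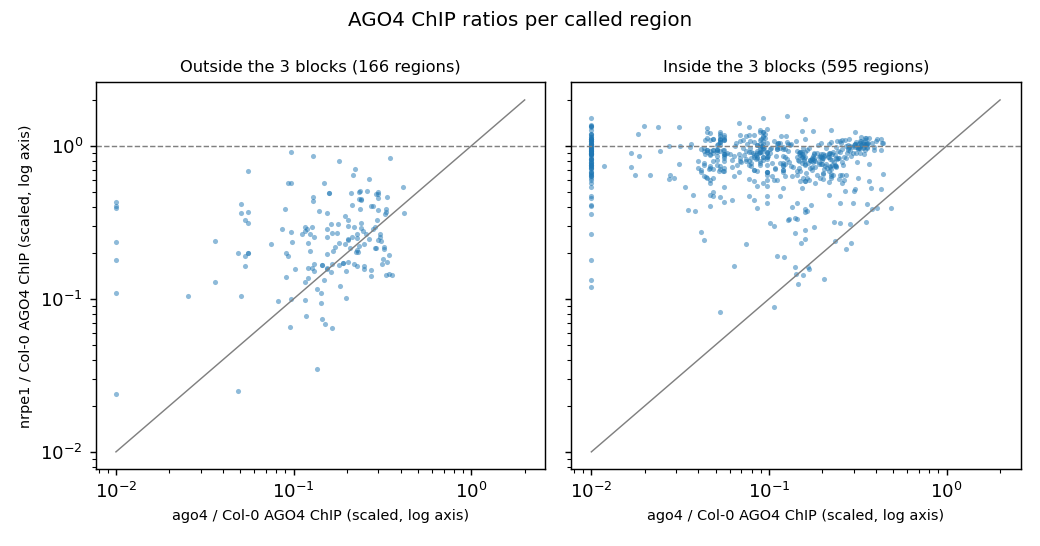
Each point is 1 called region; the horizontal axis is ago4 over Col-0 and the vertical axis nrpe1 over Col-0 AGO4 ChIP starts, both scaled and on log axes, with ratios under 0.01 drawn at 0.01. The solid line marks equal ratios and the dashed line nrpe1 equal to Col-0; the 166 regions outside the blocks have a median nrpe1 over Col-0 ratio of 0.241 and the 595 inside one of 0.850.

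Regions with the highest nrpe1 signal relative to Col-0 were, over all bins, in the blocks. The first (chromosome 3, from 14771401) was 10771 bp from its nearest gene CHR38, a chromatin remodeller gene, with 79 Col-0, 9 ago4 and 217 nrpe1 starts. Its Col-0 ChIP over input was 0.784, so Col-0 itself was not enriched there. Regions at or near AT2G07678, AT2G07632, AT2G07631, AT2G07741 and ABCI4 followed. These 5 lay on chromosome 2 between 3.2 and 3.6 Mb, a stretch where mitochondrial reads are weighed below. At these 5 at most 2.93% of Col-0 starts came from 1-hit reads, and Col-0 ChIP over input was only 1.09 to 1.22. Outside the blocks, the regions nearest to CLE4, PARP1, AT1G36745, AT5G36820, PRSL1 and AT1G36980 came first. The PARP1 region (chromosome 2, 13354401 to 13354600), within a poly(ADP-ribose) polymerase gene, had 23 Col-0, 2 ago4 and 37 nrpe1 starts, a nrpe1 over Col-0 ratio of 0.920 (0.532 to 1.62).

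The same rule applied to Col-0 against nrpe1, added after the data were seen, gave 602 regions, 477 of them outside the blocks, and 0 in reverse. The ago4 ChIP was also above nrpe1 in 139 regions outside the blocks, against 17 in reverse. Of the 166 regions above ago4, 116 overlapped a region above nrpe1. In bins, 134 were in both lists, where independent lists would share 0.272 and 20 simulated sets of unchanged libraries shared at most 0. Both comparisons use the same Col-0 library, so the lists are not independent. The simulated sets hold counting error only, so neither baseline can tell a shared loss from a bias of that library. To remove shared counting error, the Col-0 starts were split: at 196 regions called with 1 part against nrpe1, the other part exceeded ago4 by 2.50-fold (bootstrap 2.28 to 2.75), and at 126 of the 196 the exact lower bound of the ratio was above 1. Any bias of the Col-0 library is in both parts, so the split does not address it.

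The third comparison concerned the position of the regions, since the title names promoters. Outside the blocks, 108 of 166 regions (65.1%, exact interval 57.3 to 72.3) overlapped the 1 kb on either side of a protein-coding gene, against a median of 76 in 10000 random sets of bins matched on chromosome and input decile, and 0 sets reached 108. For flank bins outside any gene body the count was 74 against a random median of 29. Bodies of protein-coding genes held 51 regions against 99 in random sets, and pseudogenes, which in this annotation include transposon genes, 7 against 15. Beyond genes and flanks lay 36 regions against 24. The 477 regions above nrpe1 had 312 in flanks against 232, and 12 in pseudogenes against 37. Over all 761 regions the order was reversed, with 227 in flanks against 307 in random sets and 292 in pseudogenes against 153. Inside the blocks, with random sets drawn there, the differences were smaller, with 119 flank regions against 138 and 285 pseudogene regions against 237. The gene table gives no strand, so upstream and downstream flanks were not told apart, and the random sets describe these libraries only.

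Around the ends of 98 genes of at least 2 kb with a region within 1 kb, Col-0 ChIP over input averaged 1.31 in the outer 1 kb and peaked at 1.57 there. The ago4 and nrpe1 ChIPs averaged 0.911 and 0.779. These genes were chosen for their Col-0 excess. Around the other 12897 genes, the averages in the outer 1 kb were 0.794 in Col-0, 0.873 in ago4 and 0.773 in nrpe1, and Col-0 over ago4 ChIP averaged 0.995.

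**Figure D3:**
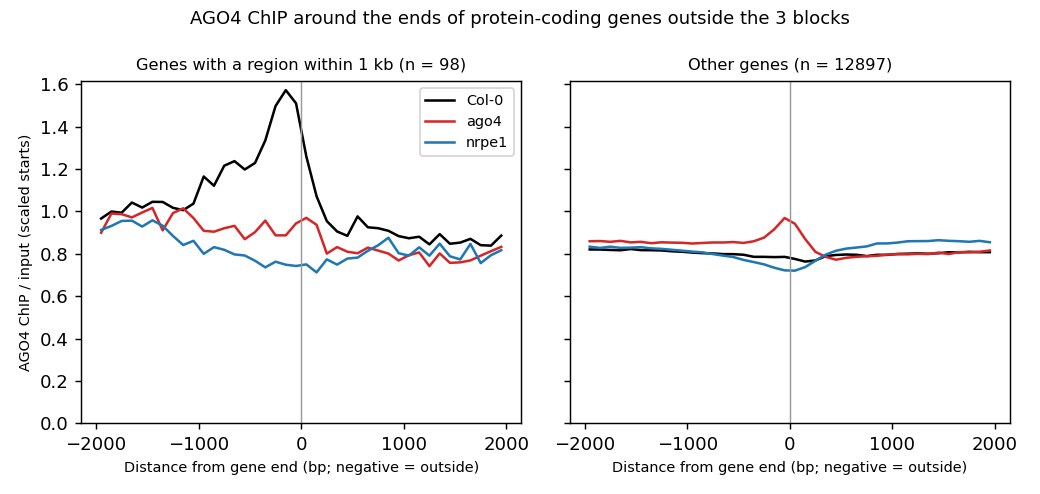
AGO4 ChIP over input (scaled starts, vertical axis) in 100-bp steps by distance from the ends of protein-coding genes outside the blocks, in bp with negative values outside the gene, both ends combined; lines are the 3 genotypes. In the 98 genes with a called region Col-0 peaks at 1.57 just outside the gene end, and in the other 12897 genes the ago4 line peaks at 0.969.

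Gene lists fixed before the data were examined were compared over their 1-kb flanks, over all bins. Of the 21 known targets of RNA-directed DNA methylation, 0 passed the bin rule over all protein-coding genes and 0 when adjusted over the list alone. Their median log2 Col-0 over ago4 ratio was 0.14, at percentile 93.4 of 10000 random lists matched on input, or 0.10 at percentile 89.8 outside the blocks. Their Col-0 over nrpe1 median stood at percentile 99.05 over flanks and 43.5 over gene bodies (99.05 and 83.2 outside the blocks). Over flanks, light-harvesting and photosystem genes stood at 98.4 (6.21 over gene bodies) and microRNA genes at 99.98. These flank medians over all bins were log2 0.20, 0.11 and 0.09. The highest of the 21 targets in Col-0 over ago4 was SDC, an F-box gene silenced through promoter repeats. It had 104 Col-0, 42 ago4 and 168 nrpe1 starts, a fold of 2.22 (1.54 to 3.26), but it lies in the chromosome 2 block and nrpe1 was at 0.924 of Col-0. AT1G58602, with 212, 106 and 242 starts, was the 1 locus of this list with a called region, 31 Col-0 starts against 1 in ago4 and 13 in nrpe1. FWA, the imprinted homeobox gene silenced by methylated repeats, had a fold of 1.05 and SUP 1.16.

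The 30 genes of the silencing machinery had 0 calls, also adjusted over the list alone, and a median of -0.03 (percentile 21.4; outside the blocks -0.05 and 20.8). Their highest member was DMS11 with 68 against 34 starts, a fold of 1.79 (1.17 to 2.79). Housekeeping, flowering and stress genes, 15 each, also had 0 calls, with medians of -0.14, -0.09 and -0.09, or -0.14, -0.10 and -0.12 outside the blocks. The highest members were ACT2, an actin gene, at 1.39, SEP3, a floral MADS-box gene in the chromosome 1 block, at 3.84, and LTI78, a cold-responsive gene, at 1.53. At SEP3 the input was itself 3.00-fold higher in Col-0 than in ago4. Among 229 cytochrome P450 genes 2 passed, CYP71B23 and CYP71B3, and 2 adjusted over the list alone. Light-harvesting and photosystem genes (45), ribosomal protein genes (44), histone genes (18), WRKY genes (67) and AGAMOUS-like MADS genes (77, of which 76 were tested) had 0. The last had a median of 0.13 at percentile 97.5, or 0.10 at 95.04 outside the blocks, but stood at 19.9 and 29.3 over gene bodies. Of 325 tested microRNA genes 1 passed, MIR4245, and their median of 0.08 stood at percentile 99.7, or 0.06 at 99.97 outside the blocks. Transfer RNA genes stood at 99.6 (99.5 outside the blocks), pseudogenes at 100 (87.8), small nucleolar RNA genes at 10.3 (47.0) and long noncoding RNA genes at 20.6 (45.5). The medians of these classes over all bins were small, at 0.04, 0.06, -0.03 and 0.02. In Col-0 over nrpe1, transfer RNA genes were at 99.8, pseudogenes and small nucleolar RNA genes at 100, and long noncoding RNA genes at 4. The medians there were also small, at log2 0.054, 0.038, 0.095 and 0.027, with 0.035 over protein-coding genes. These medians were not divided by the input fold. Over all protein-coding genes 96 of 27318 flank pairs passed, 17 of them outside the blocks. Over gene bodies, 3 members of the fixed lists passed: LTI78, with 491 Col-0, 200 ago4 and 405 nrpe1 starts and a fold of 2.20 (1.86 to 2.61), the ribosomal protein gene RPS28 at 3.61, and CYP94C1, in a block, at 2.51.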

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

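Of the tests in this part, the share of full-length reads, the frequency of reduced unenriched bins and the ChIP contrast were fixed before their results were seen, and the others were chosen after. Alignments to the organelle genomes, which no comparison uses, differed between the ChIP libraries. The mitochondrial share of rows was 0.882% in Col-0, 1.07% in nrpe1 and 0.535% in ago4, so Col-0 was 1.65 and nrpe1 2.00 times ago4. The chloroplast share was 3.29% in nrpe1, 1.04 times the 3.16% in ago4, and 2.54% in Col-0, the lowest.

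In the first pattern, the low ago4 bins, 96.8% of the 696 bins low in the ago4 ChIP on chromosomes 1 and 2 were also low in the ago4 input, the outcome set for a strain haplotype carried along with ago4-1. On chromosome 3, 0 of 315 were, yet the share of full-length rows in the ago4 ChIP changed there by -4.54 percentage points relative to Col-0, close to the -5.09 points on chromosome 2, while nrpe1 moved by 0.0596. The ago4 input moved by -1.14 points on chromosome 3 and by -2.70 on chromosome 2, where 774 of its bins were low. Its full-length share outside the blocks was 60.7%, against 80.9% in the Col-0 input, so its points are not on the ChIP scale. A haplotype in the plants of the ago4 ChIP but not, or less often, in those of the ago4 input may underlie the chromosome 3 block. Loss of AGO4 binding, which can lower a ChIP only to its background, is argued against there if background is alike: in 390 bins picked as low on a random part of the ago4 ChIP starts, the other starts over ago4 input were 0.323 (0.296 to 0.342) of the level in unenriched bins outside the blocks and 0.291 (0.266 to 0.313) of that in unenriched bins of the block, those with Col-0 ChIP over input under the genome median. Unenriched bins with ago4 under 0.5 of Col-0 were 6.38 percentage points more frequent in the block than outside, a test that by itself lay between the 2 and 10 points fixed beforehand for and against such a loss. Their share was 6.81% in this block, 5.36% in the chromosome 2 block, 2.06% in the chromosome 1 block and 0.429% outside. The bound of 10 points was thus not reached on chromosome 2 either, where the ago4 input was low too, so this test cannot decide.

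For the second pattern, the nrpe1 signal near the ago4 level outside the blocks, selection for a high Col-0 count is argued against by a Col-0 over nrpe1 fold of 4.32 (3.39 to 5.73) on Col-0 starts not used for calling. That fold covers 24 regions, those clear enough to be called on part of the reads, and leaves weaker regions untested. A loss of ChIP contrast in nrpe1 beyond that of ago4 is argued against by a nrpe1 over ago4 contrast of 1.03 (1.02 to 1.04) at 3915 bins chosen for Col-0 ChIP above input and similar Col-0 and ago4 ChIP, with median ChIP over input of 1.70 in ago4 and 1.75 in nrpe1. The 2.32 of Col-0 there is high by that choice, so the contrast of Col-0 was not compared. In 12897 genes with no region, the Col-0 over nrpe1 ratio rose from 0.983 at -1950 bp to 1.10 at -50 bp, where negative is outside the gene. A small library-wide difference at gene ends was thus present, and one as large as at the regions is argued against for these genes. Averages over genes with no region cannot exclude a bias at the ends that hold regions. The ago4 ChIP exceeded nrpe1 in 139 regions outside the blocks, against 17 in reverse. Loss of AGO4 binding alone would not place nrpe1 below ago4 if background is alike. At gene ends the 2 levels were not alike: in the outer 1 kb of the 12897 genes, ChIP over input averaged 0.873 in ago4 and 0.773 in nrpe1. The retained share takes the ago4 level as the background of nrpe1 and carries any such difference. What stays open, with 1 library per genotype, is a lower contrast of both mutant libraries than of Col-0, a weaker precipitation of AGO4 itself, a lower AGO4 amount or a bias at a few open promoters, none tested here, beside a need for Pol V.

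The third pattern was 55 regions of the initial call on chromosome 2 between 3.2 and 3.6 Mb, with a median of 1.42% of starts from 1-hit reads. Their median Col-0 over ago4 fold was 3.06, and the mitochondrial genome itself had a fold of 1.83 (1.81 to 1.85). Mitochondrial reads may contribute to these regions, but the fold lies between the bounds set for and against this as the cause, and the block there adds a second candidate.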

How the results depend on the processing

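No paired analysis was possible because each group holds 1 library. The exclusion of the 3 blocks and the rows as deposited with 1 hit were chosen after the data were seen; the other settings were planned. Settings on GC content were not run. Where a cause is not named, it was not tested.

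Values are given over all bins and then outside the blocks, against 761 and 166 regions, 190 and 138 lower in nrpe1, retained shares of 79.0 and 8.71%, and flank shares of 29.8 and 65.1%. Leaving out the blocks thus moved the regions from 761 to 166, the retained share from 79.0 to 8.71% and the flank share from 29.8 to 65.1%.

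Rows as deposited gave 22948 and 18645 regions, 4792 and 4045 lower in nrpe1, retained shares of 64.7 and 44.4% and flank shares of 46.9 and 49.3%; with 1-hit reads as deposited these were 22063 and 17855, 4721 and 3989, 54.8 and 43.8%, and 46.8 and 49.6%. Distinct starts of 1-hit reads gave 254 and 59 regions, 86 and 59 lower, 49.8 and 3.61% retained, and 25.6% in flanks over all. Bins of 100 bp gave 382 and 35 regions, 53 and 33 lower and 69.5% retained over all. Bins of 500 bp gave 310 regions outside the blocks, 328 and 244 lower, 82.9% retained and 46.3% in flanks over all. At q under 0.001, 442 and 74 regions remained past the threshold, 101 and 72 were lower, 3.78% was retained outside the blocks and 33.3% lay in flanks over all. A fold of at least 3 left 121 lower over all. Flanks of 500 bp held 23.0 and 48.2% of regions and flanks of 2 kb 39.8 and 84.3%, by their size. The held-out starts gave 74.8 and -6.05% retained, the latter with an interval of -15.6 to 3.17.

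Col-0 ChIP against Col-0 input gave 5922 and 4000 regions, 694 and 553 lower, and 18.5 and 21.2% in flanks. Its retained shares of -201 and -2557% have no use, since regions were not chosen for a Col-0 excess over ago4, the divisor.

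The remaining settings (median scaling, a fold of 1.5, no shift, no input minimum, no input division, thinning and the exclusion of 2 Mb on either side of AGO4) kept the counts of regions and of regions lower in nrpe1 within 1.5 times, and the retained and flank shares within their intervals. Other counts moved further: reverse regions went from 67 to 161 (51 to 124 outside the blocks) with no input division, to 114 (88) at a fold of 1.5, and to 12 (3) with distinct starts of 1-hit reads. Protein-coding flank pairs called outside the blocks went from 17 to 26 with median scaling, and the cause was not tested. Over gene bodies 3 members of the fixed lists passed, against 2 over flanks and 2 with median scaling. Depth limits the calls: changes of 3-fold were mostly missed in simulated counts.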

Other observations

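Outside the blocks, 166 protein-coding genes had a region in the body or within 1 kb, and 115 of them had one in a flank. Gene-poor windows, the fifth of 500-kb windows with the least protein-coding sequence, held 33 regions, or 2.61 per tested Mb, against 1.65 per Mb elsewhere. Of the 166 regions, 102 had most of their Col-0 starts from 1-hit reads, with a median Col-0 over ago4 fold of 7.67, and 64 had most from reads with several hits, with a median of 3.94. The retained share in nrpe1 was 8.17% in the former (5.23 to 11.5) and 9.51% in the latter (2.92 to 16.1). The ago4 ChIP exceeded the nrpe1 ChIP in 175 bins (139 regions) outside the blocks, and nrpe1 exceeded ago4 in 17.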
